A study of Mus musculus with 9 samples.

How the data were processed

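Gene expression was measured by poly-A RNA sequencing (paired-end reads, Illumina NovaSeq) in 9 libraries that the labels describe as RAW264.7, a mouse macrophage-like line from BALB/c mice. The labels put 3 libraries in each of 3 groups: untreated, TNF (tumour necrosis factor alpha for 24 h), and TNF plus WBG (Wang Bi granules, a Chinese herbal preparation, given with tumour necrosis factor alpha for 24 h). The values used here are the FPKM of the deposited gene table (fragments per kilobase of gene model and M (mega) fragments, made by the authors), with 1 value per Ensembl gene and library for 56289 gene identifiers. The aligner, the program that made the FPKM, its annotation and the genome build are not given in the sources used here, so no coordinates are printed. Identifiers were matched to symbols through GENCODE M21: 55144 matched and 1145 did not, 10 of the latter among the genes tested.

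The file holds no counts. Depth was therefore inferred: FPKM times exon length of single-exon genes piled up on multiples of a step in each library, with 26.4 to 29.9% of values within 0.02 of a whole step where evenly spread values would give 4%. If a step is 1 fragment, the libraries hold 18.9 to 26.1 M fragments. No count was derived for any gene and no counting interval is given. The sum of FPKM per library ran from 427781 to 436809, and 12611 to 12737 genes reached 1 FPKM.

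Genes with an FPKM of at least 1 in at least 3 of the 9 libraries, of any group, were kept (13026 genes). The log2 of FPKM plus a pseudocount of 1 was fitted with limma 3.58.1 (R 4.3.3), with a trend of the spread on expression, all 9 libraries in 1 fit and group as the only term. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. The 3 comparisons were TNF against untreated, TNF plus WBG against TNF, and TNF plus WBG against untreated. Errors beside FPKM means are SD (n = 3), and errors beside log2 fold changes are standard errors of the fit. Fold values are ratios of mean FPKM, given only where both means were at least 1. Log2 fold changes hold the pseudocount and are therefore smaller than the ratio for genes near 1 FPKM.

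A total of 34 gene lists (pathways, treatment responses, cell type markers and technical groups) were fixed before the data were examined, and 30 of them had at least 5 genes kept and were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. Counts within a list are given over all genes tested and also adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives. The genes named in the text follow a rule fixed at the same time. It takes the 5 largest rises and 5 largest falls among called genes whose groups do not overlap, with a mean of at least 5 FPKM in the higher group and without predicted or clone names. From each list described it takes up to 2 called members per direction, or the 1 with the largest absolute change where none was called. It adds 11 genes given always in the first 2 comparisons (Tnf, Il1b, Il6, Ptgs2, Nos2, Ccl2, Mmp9, Nfkbia, Tnfaip3, Hmox1 and Gapdh), and the genes called in opposite directions by TNF and by WBG. Genes outside this rule are said to be chosen after their values were seen.

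The count of genes moved in opposite directions by TNF and by WBG was set beside 100 simulations, since both comparisons share the TNF libraries. The spread was that of the fit, and noise was drawn independently for each gene and library. Real genes vary together, so the range over these simulations may be too narrow. One set held no group differences, and another held the TNF effects with no WBG effect.

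The pipeline was tested on simulated data with the spread of these libraries, 200 changed genes in each of 3 runs. At a log2 change of 0.25 it recovered 12 to 18% of the changed genes. At a log2 change of 0.5 it recovered 66 to 68%, and at a log2 change of 1 it recovered 90 to 96%. Runs with fewer changed genes were not made. These percents may therefore be too high for TNF plus WBG against TNF, where 13 genes were called. Of the calls, 7 of 140 were false for TNF against untreated and 9 of 150 for TNF plus WBG against untreated. For TNF plus WBG against TNF 15 of 155 were false, a share above the adjusted p threshold.

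Alternatives, nearly all chosen before the data were examined, were pseudocounts of 0.1 and 5, no filter, a stricter filter (mean FPKM of at least 5), median-ratio scaling, quantile normalization, a fit of only the 6 libraries compared, limma without trend, robust limma, a replicate block, a 2-fold minimum, and omission of each library in turn. No library and no column was left out. Analyses and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.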

Results

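RNA of 9 mouse libraries labelled RAW264.7 was sequenced, 3 per group: untreated, TNF (tumour necrosis factor alpha for 24 h) and TNF plus WBG (Wang Bi granules together with tumour necrosis factor alpha for 24 h). The series asks which genes differ among blank, induced and drug-treated cells, as a way to the mechanism of Wang Bi granules in rheumatoid arthritis. The inferred depth, if the smallest step of the values is 1 fragment, was 22.6 ± 3.1 M (mega) fragments in the untreated group, 20.8 ± 1.8 M in the TNF group and 21.2 ± 2.1 M in the TNF plus WBG group (SD, n = 3). Correlation of log2 values across genes was 0.987 to 0.989 within groups, 0.986 to 0.989 between TNF and TNF plus WBG, and 0.979 to 0.982 between untreated and treated libraries. Genes are not independent replicates in these correlations. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples.

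The libraries carried fibroblast transcripts at high levels and few macrophage transcripts. Of 20 macrophage identity genes fixed beforehand, 5 had a mean of at least 1 FPKM, and the median of the list was 0.02 FPKM. Ptprc (the leukocyte antigen CD45), Itgam (CD11b) and Adgre1 (F4/80) were listed at 0 in all 9 libraries. Csf1r, the receptor of macrophage colony-stimulating factor, was at most 0.07 FPKM, Spi1 (PU.1) at most 0.05 FPKM, and Lyz2 lay between 0.31 and 0.68 FPKM. Of 14 fibroblast markers, 11 reached a mean of at least 1 FPKM, with a median of 72.7 FPKM. Col1a1 lay between 791 and 1021 FPKM, Col3a1 between 613 and 668 FPKM, and Fn1 between 694 and 899 FPKM. Loxl1 (mean 0.83 FPKM), Thy1 (at most 0.07 FPKM) and Lum (listed at 0) did not. No gene of the lymphocyte, epithelial and endothelial, or neutrophil and mast cell lists reached a mean of 1 FPKM. All 3 groups had this profile, so each comparison here was made between libraries of this kind. The single genes named in this paragraph were picked from the fixed lists after their values were seen.

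**Figure D1:**
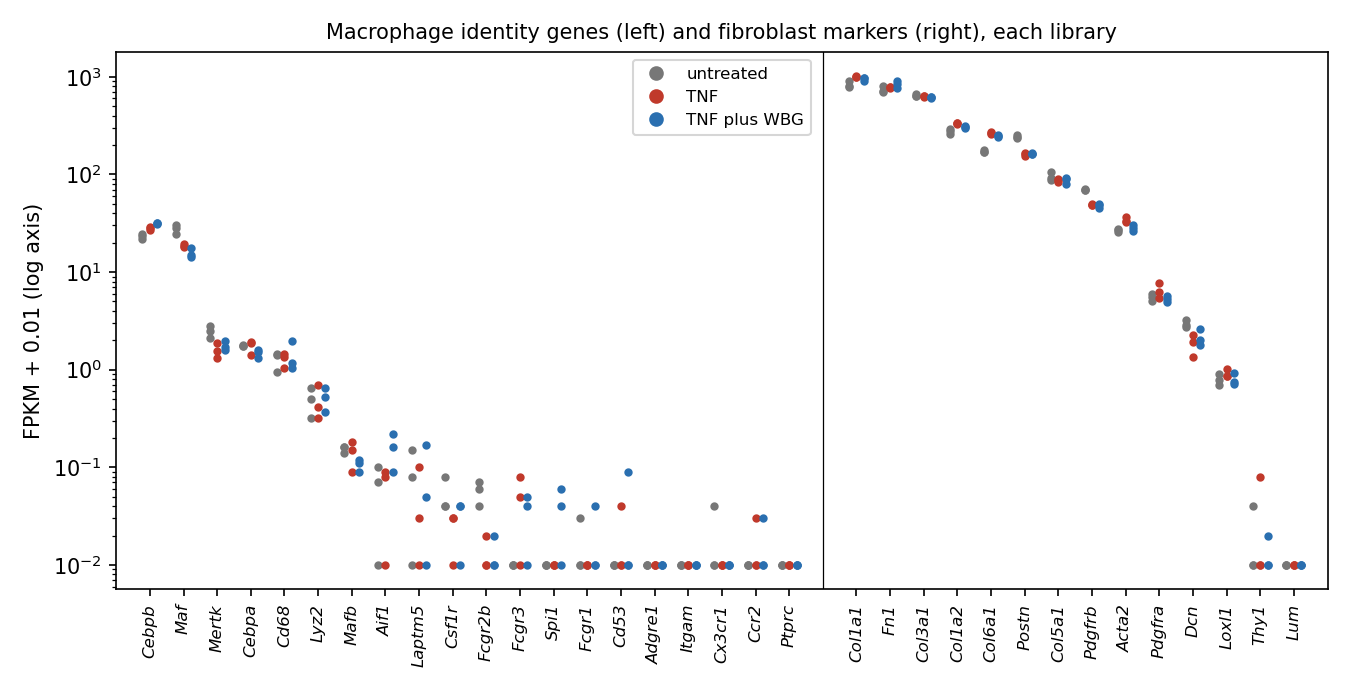
FPKM (log axis, 0.01 added so that 0 can be drawn) of the macrophage identity genes, left, and the fibroblast markers, right, with 1 point per library coloured by group. Ptprc, Itgam and Adgre1 sit at 0 in all 9 libraries, and Col1a1 lies between 791 and 1021 FPKM.

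TNF against untreated asks what the cytokine did without WBG. The labels give 24 h for the TNF libraries and no time for the untreated ones. A difference in time in culture therefore cannot be told apart from the effect of TNF here. C3, the central complement component (ENSMUSG00000024164), rose from 8.77 ± 0.71 to 167 ± 6.84 FPKM (SD, n = 3), 19.0-fold, with a log2 fold change of 4.10 ± 0.06. Ccl2, a monocyte-attracting chemokine (ENSMUSG00000035385), rose 7.37-fold from 36.0 ± 2.86 to 265.2 ± 3.51 FPKM. Cd74, the invariant chain of MHC class II, rose 13.7-fold to 15.0 ± 0.68 FPKM. Ubd, a ubiquitin-like modifier, reached 15.7 ± 0.79 FPKM (log2 fold change 3.20), and Serpina3g, a serine protease inhibitor, reached 8.19 ± 0.43 FPKM (2.74). Among the falls, the potassium channel Kcna1 went from 26.8 ± 0.86 to 5.61 ± 0.41 FPKM (log2 fold change -2.07), and the neuronal tubulin Tubb3 from 55.3 ± 2.30 to 16.1 ± 0.56 FPKM (-1.72). Btc, an EGF receptor ligand (-1.98), Sema4f, a semaphorin (-1.63), and the stress-induced transcription factor Atf3 (-1.55) fell as well.

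Genes of the NF-kB and TNF response rose together: 20 of 26 measured members rose, none fell and 6 did not pass the test (22 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.9e-19). They included the inhibitors Nfkbia (3.25-fold, log2 1.66) and Nfkbie (5.91-fold, 2.35), the NF-kB subunit Relb (4.52-fold, 1.98) and the deubiquitinase Tnfaip3 (3.17-fold, 1.44). Of 7 measured chemokines 6 rose, also adjusted over the list alone, and 1 did not pass (camera adjusted p = 7.32e-12). Cxcl10, an interferon-induced chemokine, reached 6.70 ± 0.77 FPKM. Of 16 antigen presentation and costimulation genes 12 rose and 4 did not pass (14 rose adjusted over the list alone; camera adjusted p = 1.89e-17), among them Cd74 and the class I gene H2-Q4 (4.02-fold, log2 1.93). Of 21 interferon-stimulated genes 12 rose and 9 did not pass (16 rose adjusted over the list alone; camera adjusted p = 4.36e-11), among them Parp14 (2.39-fold) and the guanylate-binding protein Gbp3 (2.83-fold). The count of 12 became 6 without untreated replicate 1 and 7 without untreated replicate 3. These 4 lists also passed with an estimated correlation, at adjusted p = 0.00135, 0.0216, 0.0123 and 0.00421 in the order given. No other list did in this comparison.

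**Figure D2:**
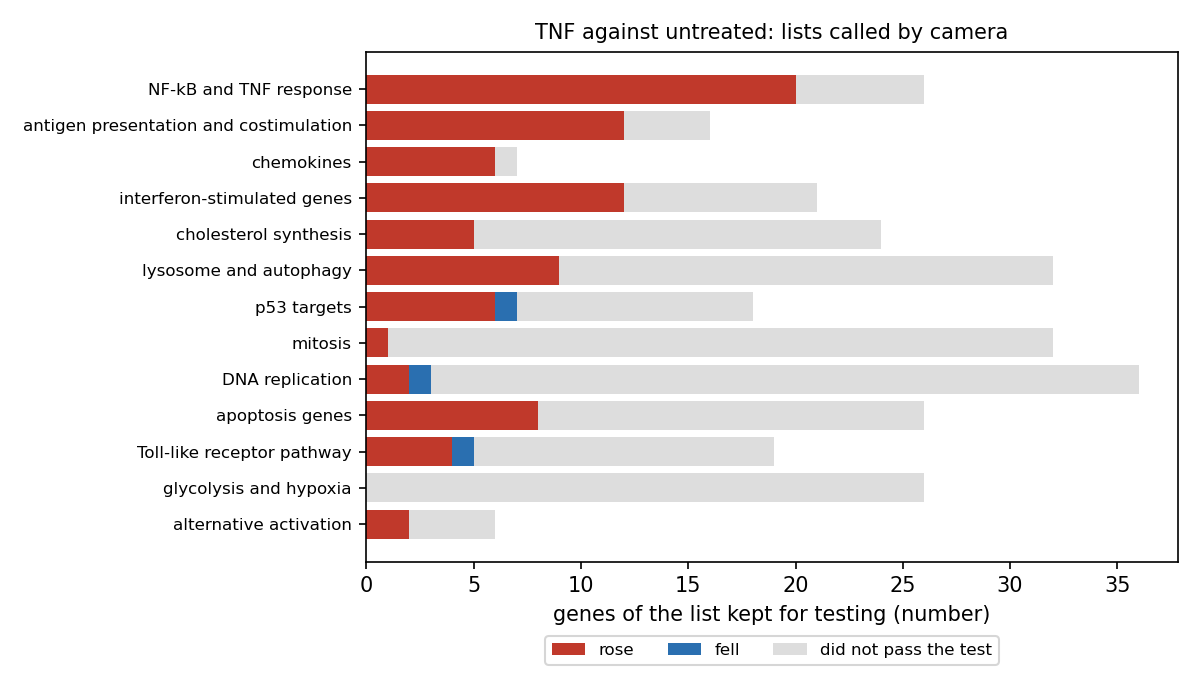
Number of measured genes of each list that rose, fell or did not pass the test between TNF and untreated, for the 13 lists called by camera at the preset correlation. In the NF-kB and TNF response list 20 of 26 genes rose.

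Of the products often measured after TNF, Tnf and Il1b were listed at 0 in all libraries, Il6 had group means of at most 0.03 FPKM, and Nos2 was too low to be tested (0.42 ± 0.07 FPKM with TNF). Ptgs2, the inducible cyclooxygenase, had 5.22 ± 0.59 FPKM without and 4.24 ± 0.32 FPKM with TNF (log2 -0.25, adjusted p = 0.143). Hmox1, heme oxygenase 1, had a log2 fold change of 0.23 (adjusted p = 0.258) and Gapdh of 0.05 (adjusted p = 0.858). Among 8 cytokines, Csf1, macrophage colony-stimulating factor, rose 2.58-fold to 55.9 ± 4.0 FPKM, and Spp1 (osteopontin) fell by 0.19 on the log2 scale. The other 6 did not pass (2 rose and 1 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.198). Without untreated replicate 1, 2 cytokines rose. Of 16 matrix proteases and inhibitors 5 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.334). Mmp9, gelatinase B, went from 0.18 ± 0.04 to 4.14 ± 0.17 FPKM (log2 2.12), Adam19 rose by a log2 of 0.56, and the inhibitor Timp3 changed by a log2 of -0.35. Without TNF replicate 3, 2 of this list fell. Of 5 complement and Fc genes, C3 and Cfb rose (camera adjusted p = 0.102; 2 rose and 1 fell adjusted over the list alone), and the mean of the list (0.93) lay far above its median (0.10).

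In the list of MAPK pathway and immediate early genes 5 of 35 rose and 9 fell (5 and 12 adjusted over the list alone; camera adjusted p = 0.0573). Jun fell by 1.31 and Fos by 0.85 on the log2 scale, while the p38 kinase genes Mapk11 (0.82) and Mapk12 (0.48) rose. Without untreated replicate 3 or TNF replicate 3, 5 of this list fell. Of 18 genes in the list of p53 targets, which also holds the p53 gene Trp53 itself, 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000346; adjusted p = 0.149 with an estimated correlation). Plk2 (log2 0.98) and Trp53 (0.58) were up and Sesn1 (-0.36) was down. Of 26 apoptosis genes 8 rose (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00754; adjusted p = 0.0893 with an estimated correlation), among them the death receptor Fas (5.17-fold). Of 19 Toll-like receptor pathway genes 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0122; adjusted p = 0.221 with an estimated correlation), with Tlr2 (3.38-fold) and Lbp (1.81-fold) up. The 1 fall was kept only in the omission of untreated replicate 2, and each of the 8 other omissions gave 0. Of 30 unfolded protein and integrated stress response genes 7 rose, Nupr1 (log2 0.78) and Ddit3 (0.41) among them, and Atf3 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.113). The count of 7 became 4 without untreated replicate 1, TNF replicate 3 or TNF plus WBG replicate 2, 3 without untreated replicate 3 or TNF replicate 1, and 2 without TNF replicate 2. Without untreated replicate 1, 2 of that list fell. Of 22 heat shock chaperones 4 fell, also adjusted over the list alone (camera adjusted p = 0.0799), among them Cryab (-0.82) and Hspd1 (-0.26). Of 24 PI3K-AKT-mTOR genes 3 rose, Pik3r5 (0.83) and Foxo3 (0.37) among them, also adjusted over the list alone (camera adjusted p = 0.318).

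Of 24 cholesterol synthesis genes 5 rose (8 adjusted over the list alone; camera adjusted p = 2.45e-06; adjusted p = 0.198 with an estimated correlation), among them Fdps and Mvk (both 1.33-fold). The count of 5 became 3 without untreated replicate 2, untreated replicate 3 or TNF replicate 1, and 2 without TNF replicate 3. Of 32 lysosome and autophagy genes 9 rose (14 adjusted over the list alone; camera adjusted p = 6.12e-05; adjusted p = 0.149 with an estimated correlation), among them Gla (1.35-fold), and 5 rose without untreated replicate 1, untreated replicate 2 or TNF replicate 2. DNA replication had 2 rises and 1 fall among 36 genes (1 and 1 adjusted over the list alone; camera adjusted p = 0.00268; adjusted p = 0.273 with an estimated correlation), with Uhrf1 up by a log2 of 0.36. The rises became 1 without untreated replicate 1, 2 or 3, TNF replicate 3, or TNF plus WBG replicate 1 or 2, and the falls 0 without untreated replicate 3. Mitosis had 1 rise, Top2a, among 32 genes (0 adjusted over the list alone; camera adjusted p = 0.00147; adjusted p = 0.388 with an estimated correlation). The call of Top2a was lost without each untreated or TNF replicate (adjusted p up to 0.0932, without untreated replicate 1) and with the replicate block (0.0565). Of 6 alternative activation genes Stab1 (2.00-fold) and Tgm2 (1.40-fold) rose, also adjusted over the list alone (camera adjusted p = 0.0277; adjusted p = 0.149 with an estimated correlation; 0.0517 without untreated replicate 1 and 0.0663 without TNF replicate 2). No gene of 26 in glycolysis and hypoxia passed, also adjusted over the list alone, and its camera adjusted p of 0.0122 (adjusted p = 0.59 with an estimated correlation) became 0.203 without untreated replicate 3 and 0.077 without TNF replicate 2. In that list 1 gene rose without TNF plus WBG replicate 2 and 2 without TNF plus WBG replicate 3. The remaining lists were not called by camera. These are osteoclast genes (3 rose and 1 fell of 10; adjusted p = 0.0748), NRF2 and antioxidant genes (3 and 1 of 28; 0.206), aryl hydrocarbon receptor genes (1 and 1 of 5; 0.227), eicosanoid and nitric oxide enzymes (1 and 1 of 11; 0.958), LXR targets and lipid handling (2 and 0 of 14; 0.958), oxidative phosphorylation (2 and 3 of 34; 0.283), and cytosolic ribosomal proteins (1 and 3 of 40; 0.306). Many of these small counts depended on single libraries. The LXR rises became 0 without untreated replicate 3 or TNF replicate 3, and 1 without untreated replicate 1 or 2 or TNF replicate 1 or 2. For oxidative phosphorylation the rises became 0 without untreated replicate 1, 2 or 3 or TNF replicate 2 or 3 and 1 without TNF replicate 1 or TNF plus WBG replicate 1 or 2, and the falls 1 without untreated replicate 1 or TNF replicate 2. For ribosomal proteins the falls became 0 without untreated replicate 1 or 3 or TNF replicate 3 and 1 without TNF replicate 1 or 2, and the rises 0 without untreated replicate 2 or 3 or TNF replicate 2 or 3 and 2 without TNF replicate 1. For aryl hydrocarbon receptor genes the rises became 0 without untreated replicate 1 or TNF replicate 2 or 3, and the falls 0 without untreated replicate 2 or 3 or TNF replicate 1 or 3. The NRF2 falls became 0 without untreated replicate 1 or 3, TNF replicate 1 or 3, or TNF plus WBG replicate 1 or 2. The eicosanoid falls became 0 without TNF replicate 2 or 3, and the rises 2 without untreated replicate 3. Adjusted over the list alone the counts of the lists not called were 3 and 1, 5 and 3, 1 and 1, 2 and 1, 2 and 0, 2 and 4, and 1 and 3. No mitochondrially encoded RNA of 13 passed, also adjusted over the list alone (camera adjusted p = 0.652), nor did any of the 4 measured replication-dependent histones, a list too small to test (0 rose and 1 fell adjusted over the list alone).

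Fibroblast markers moved both ways, with 4 of 11 up and 2 down (4 and 3 adjusted over the list alone; camera adjusted p = 0.712). Col6a1 rose from 172 ± 4.39 to 267 ± 6.46 FPKM and Acta2 by a log2 of 0.34, while Postn fell from 242 ± 9.14 to 161 ± 4.31 FPKM and Pdgfrb from 70.0 ± 1.31 to 48.8 ± 0.57 FPKM. Of the 5 measured macrophage identity genes, Cebpb rose (1.21-fold), Maf fell by 0.54 and Mertk by 0.42 on the log2 scale (1 and 2 adjusted over the list alone; camera adjusted p = 0.451). The call of Mertk was lost in 7 of the 9 omissions of a library (adjusted p up to 0.146; without untreated replicates 2 and 3, TNF replicates 1 and 3, and each TNF plus WBG replicate).

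Of 13026 genes, 1386 passed between TNF and untreated (limma, adjusted p under 0.05), 837 up and 549 down, and 124 of these changed at least 2-fold. The 3 libraries of each group did not overlap for 3902 genes, where chance gives 10% of the genes. Exons of Cd74, Cxcl10, H2-Q4, Parp14, Cfb, Spp1, Adam19, Timp3, Jun, Ddit3, Cryab, Hspd1, Fdps, Top2a, Stab1, Tgm2, Maf and Cebpb overlap another annotated gene in GENCODE M21. Without TNF replicate 3 the count was 920.

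TNF plus WBG against TNF asks what the granules added to TNF. Saa3, an acute-phase protein, was listed at 0 in untreated libraries and rose from 1.31 ± 0.47 to 7.02 ± 1.28 FPKM (SD, n = 3), a log2 fold change of 1.81 ± 0.16 (adjusted p = 0.00514). Cxcl1, a neutrophil-attracting chemokine, rose 2.29-fold from 10.4 ± 0.99 to 23.9 ± 3.16 FPKM (adjusted p = 0.00514). Steap4, a metalloreductase, rose 1.81-fold from 25.6 ± 0.46 to 46.3 ± 4.97 FPKM (adjusted p = 0.00399). Tfrc, the transferrin receptor that takes up iron, rose 1.74-fold from 40.7 ± 3.50 to 71.1 ± 2.89 FPKM (adjusted p = 0.00384). The largest fall was that of Tmem184b, a membrane protein gene (ENSMUSG00000009035), from 45.1 ± 0.85 to 16.5 ± 0.91 FPKM (log2 fold change -1.40 ± 0.05, adjusted p = 1.3e-05).

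The other genes that rose were Zmym1, a zinc finger protein gene (3.20-fold, adjusted p = 0.00384), Actr3, a subunit of the actin-nucleating Arp2/3 complex (1.28-fold, 0.00514), Spp1 (1.26-fold, 0.00917), Armt1 (1.94-fold, 0.0476) and Cbr2, a carbonyl reductase (1.27-fold, 0.0476). Abr (log2 -0.60, 0.0239), Afg3l1, a mitochondrial protease gene (-0.46, 0.0326), and 2210412B16Rik (-0.74, 0.0363) fell. Tfrc, Actr3, Cbr2 and 2210412B16Rik lie outside the rule for named genes and were chosen after their values were seen. Exons of Zmym1, Spp1 and Abr overlap another annotated gene. Of the genes given always, Ccl2 (log2 -0.17, adjusted p = 0.491), Mmp9 (-0.32, 0.376), Nfkbia (-0.09, 0.649), Tnfaip3 (0.23, 0.735), Ptgs2 (-0.08, 0.859), Hmox1 (0.26, 0.556) and Gapdh (0.23, 0.644) did not pass. Tnf and Il1b were listed at 0, Il6 stayed at 0.03 FPKM or less on average, and Nos2 had 1.02 ± 0.74 FPKM and was not tested.

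**Figure D3:**
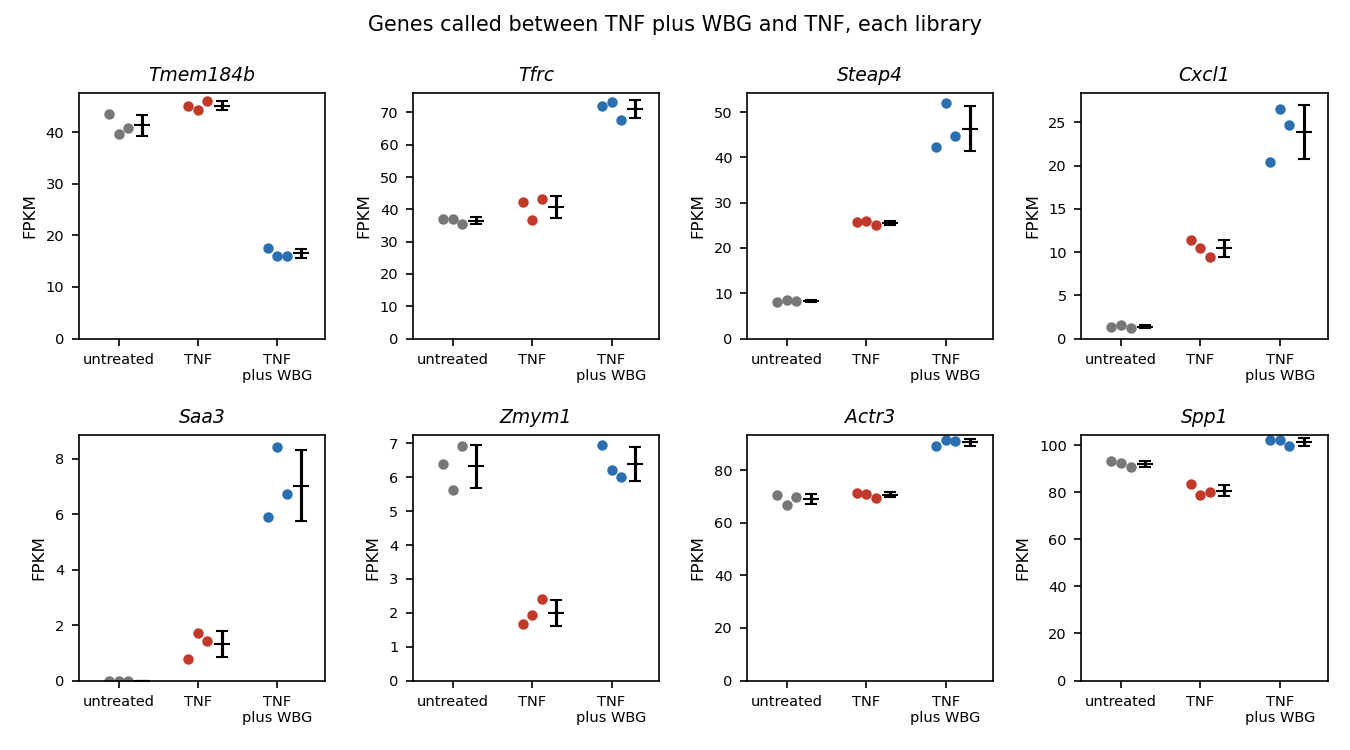
FPKM of the 8 genes with the smallest adjusted p between TNF plus WBG and TNF, with 1 point per library and, beside the points, the group mean with its SD (n = 3). Tmem184b fell from 45.1 to 16.5 FPKM, and Cxcl1 rose from 10.4 to 23.9 FPKM.

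By list, camera at the preset correlation called 7 of 30, and none of these passed with an estimated correlation. Of 26 glycolysis and hypoxia genes 24 were higher and 0 passed (0 adjusted over the list alone; camera adjusted p = 1.33e-08; adjusted p = 0.465 with an estimated correlation). Ak4, with the largest change, varied widely with WBG (10.6 ± 11.4 FPKM). Of 36 DNA replication genes 32 were lower and 0 passed (1 fell adjusted over the list alone; camera adjusted p = 1.33e-08; adjusted p = 0.266 with an estimated correlation), and Fen1, with the largest change, went the other way (log2 0.92, adjusted p = 0.662). With TNF alone 32 of these genes were higher than in untreated libraries. Between TNF plus WBG and untreated 18 were higher and 18 lower (camera adjusted p = 0.49). Both other comparisons share the TNF libraries, and these genes vary together. A deviation common to the TNF libraries could therefore give both counts of 32. Of 13 mitochondrially encoded RNAs 12 were lower and 0 passed (2 fell adjusted over the list alone; camera adjusted p = 6.27e-05; adjusted p = 0.465 with an estimated correlation), with mt-Nd3 at a log2 of -0.33. On the second principal component TNF plus WBG replicate 3 (5.4) lay within the range of the TNF libraries (0.6 to 12.8), while TNF plus WBG replicates 1 and 2 lay at -13.9 and -10.5. TNF plus WBG replicate 2 stood apart on the third principal component (-16.3, the others -10.4 to 6.7) and had the lowest mitochondrial share of FPKM (6.81%). Without it the camera adjusted p was 0.000312 for glycolysis and hypoxia, 3.84e-05 for DNA replication and 0.0301 for the mitochondrially encoded RNAs. Of 16 antigen presentation and costimulation genes 13 were lower and 0 passed (3 fell adjusted over the list alone; camera adjusted p = 0.000243; adjusted p = 0.266 with an estimated correlation), with Cd74 at 10.2 ± 1.55 FPKM against 15.0 ± 0.68 FPKM with TNF (adjusted p = 0.263).

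Of 24 cholesterol synthesis genes 18 were higher and 0 passed (0 adjusted over the list alone; camera adjusted p = 0.00304, 0.135 without TNF replicate 2; adjusted p = 0.465 with an estimated correlation), with Acat2 at a log2 of 0.49. All 8 measured cytokines were higher and Spp1 rose (1 rose adjusted over the list alone; camera adjusted p = 0.00992, 0.0855 without TNF plus WBG replicate 2; adjusted p = 0.266 with an estimated correlation). Of 21 interferon-stimulated genes 17 were lower and 0 passed (3 fell adjusted over the list alone; camera adjusted p = 0.021; adjusted p = 0.266 with an estimated correlation). That call was lost without TNF replicate 2 (0.12), TNF replicate 3 (0.0565) or TNF plus WBG replicate 3 (0.137). Among the lists not called, the NF-kB and TNF response had 0 of 26 genes past the test, also adjusted over the list alone (camera adjusted p = 0.245), and the largest change was that of Ier3 (log2 0.49, adjusted p = 0.411). Of 30 unfolded protein and integrated stress response genes 0 passed (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0727, fry adjusted p = 0.00201), and Ero1l had the largest change (log2 0.43, adjusted p = 0.55). In the chemokine list Cxcl1 rose and the 6 others were lower without passing (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.0727).

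With limma 13 of 13026 genes passed, 9 up and 4 down, and 4 of these changed at least 2-fold. An unadjusted p under 0.05 was reached by 1180 genes where chance gives 651, and the groups did not overlap for 1921 genes (14.7% where chance gives 10%). Leaving out 1 library at a time kept Tmem184b, Steap4, Tfrc, Actr3, Cxcl1, Saa3 and Zmym1 in all 9 omissions, and the count was 8 without untreated replicate 1. Spp1 was lost without TNF replicate 2, TNF replicate 3 or TNF plus WBG replicate 1 (adjusted p up to 0.0647), and Abr, Afg3l1, Cbr2, Armt1 and 2210412B16Rik were kept in 3, 2, 1, 1 and 1 omissions (adjusted p up to 0.145, 0.186, 0.192, 0.192 and 0.187, each highest without TNF replicate 3).

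How far WBG moved what TNF had moved was asked of the genes called in both comparisons, 8 in all. Of these, 4 went in opposite directions and 4 in the same direction. Zmym1 fell with TNF from 6.32 ± 0.65 to 2.00 ± 0.38 FPKM and stood at 6.40 ± 0.50 FPKM with TNF plus WBG. Spp1 went from 91.9 ± 1.30 to 80.7 ± 2.41 and then 101 ± 1.51 FPKM, and Armt1 from 8.12 ± 1.61 to 5.58 ± 0.45 and then 10.8 ± 0.42 FPKM. Afg3l1 went up from 14.8 ± 0.63 to 19.8 ± 0.06 FPKM with TNF and stood at 14.2 ± 1.00 FPKM with TNF plus WBG. The TNF call of Armt1 (adjusted p = 0.0361) was lost without untreated replicate 3 and without each TNF or TNF plus WBG replicate, up to 0.114 without TNF replicate 2. The count of opposite genes was 7 without TNF replicate 1, and 2 without untreated replicate 1 or 3, TNF replicate 2, or TNF plus WBG replicate 1 or 3. Cxcl1, Steap4, Saa3 and Cbr2 rose with TNF and rose further with WBG.

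Across all 1386 genes called with TNF, 1053 (76.0%) moved the opposite way with WBG. Both comparisons share the TNF libraries, which alone gives a mean of 62.5% and at most 65.3% in 100 simulations with the TNF effects and no WBG effect. The simulated genes vary independently, unlike real ones, so the simulated ranges here may be too narrow to judge chance by. The size of this shift was small, 6.7% of the TNF change, and 1 of 100 simulations gave as much (the highest was 8.2%). With genes weighted by precision, a weighting chosen after results were seen, it was 10.9%, where the simulations gave a mean of 1.3% and at most 2.0%. Of the TNF-raised genes 76.5% were lower with WBG, and of the TNF-lowered genes 75.2% were higher. For the genes called in both comparisons, the simulations with the TNF effects and no WBG effect gave means of 0.04 opposite and 0.02 same-direction genes, at most 1 of each, and independent lists of these sizes give 0.26, 0.38, 0.58 and 0.17 genes (up then down, down then up, up in both, down in both). The correlation of the 2 sets of fold changes over all genes was -0.35, and genes are not independent replicates in it. Simulations with no group differences, and so without TNF effects, gave -0.50 through the shared libraries. They do not give the correlation to expect with TNF effects and no WBG effect, so -0.35 cannot be read as weaker than that. The covariance was -0.0150 against -0.0094 in the simulations with no group differences.

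**Figure D4:**
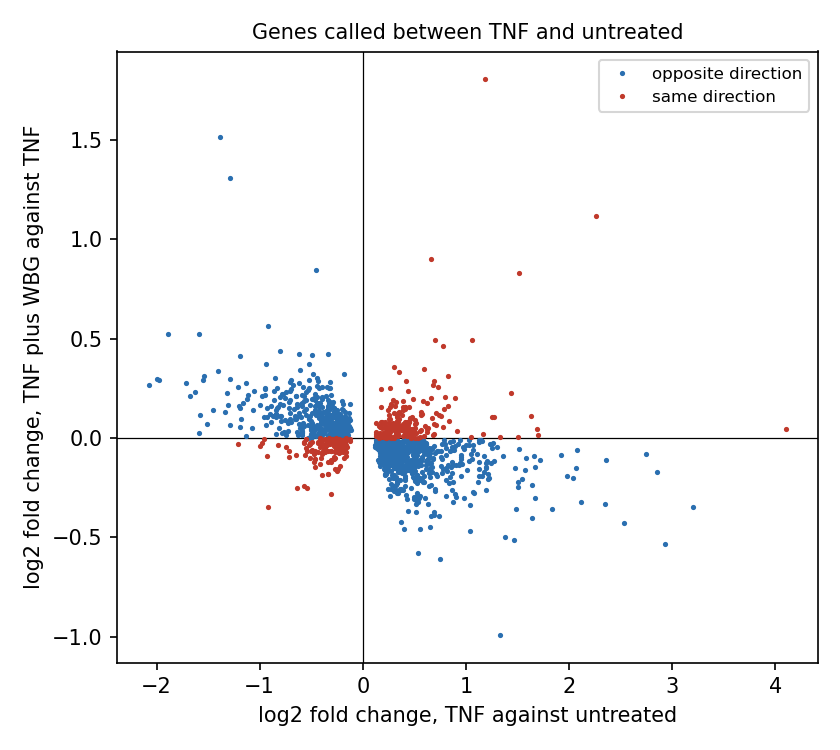
Log2 fold change with TNF (TNF against untreated, x axis) and with WBG (TNF plus WBG against TNF, y axis) of the 1386 genes called between TNF and untreated, 1 point per gene. Blue genes, 1053 of them, moved in opposite directions.

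TNF plus WBG against untreated gives the joint effect, again with no time given for the untreated libraries. C3 rose 19.6-fold to 172 ± 8.05 FPKM (SD, n = 3), Ccl2 6.55-fold and Cxcl1 17.4-fold, Saa3 rose from a listed 0 to 7.02 ± 1.28 FPKM, and Ubd reached 12.2 ± 1.19 FPKM. Kcna1 (log2 -1.81), Btc (-1.69), Fam19a5 (-1.44), Tubb3 (-1.44) and Sema4f (-1.39) had the largest falls taken by the rule. In the NF-kB and TNF response 20 of 26 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 4.92e-19), with Nfkbie and Relb at 4.68-fold and 3.91-fold. The 1 fall was kept only without TNF replicate 1 or TNF plus WBG replicate 3, and the 7 other omissions gave 0. Of 7 chemokines 6 rose, also adjusted over the list alone (1.05e-10). Of 16 antigen presentation genes 11 rose (13 adjusted over the list alone; 1.87e-17), among them Cd74 (9.22-fold) and H2-Q4 (3.79-fold). Of 21 interferon-stimulated genes 7 rose (12 adjusted over the list alone; 1.03e-09), among them Gbp3 (2.77-fold) and Zbp1 (2.81-fold). Of 26 apoptosis genes 6 rose (11 rose and 1 fell adjusted over the list alone; 0.00104), among them Fas (5.29-fold) and Bbc3 (1.44-fold). These 5 lists also passed with an estimated correlation, at adjusted p = 0.00139, 0.0281, 0.0123, 0.00636 and 0.0427 in the order given.

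Cholesterol synthesis and glycolysis had more calls here than with TNF alone, a difference between counts that was not itself tested. Of 24 cholesterol synthesis genes 13 rose (19 adjusted over the list alone; camera adjusted p = 1.34e-10; adjusted p = 0.114 with an estimated correlation), among them Mvd (1.43-fold). The count of 13 became 7 without untreated replicate 1 or 3, 8 without TNF plus WBG replicate 1 and 6 without TNF plus WBG replicate 2. Of 26 glycolysis and hypoxia genes 6 rose (16 adjusted over the list alone; camera adjusted p = 5.22e-09; adjusted p = 0.25 with an estimated correlation), among them Egln3 (1.48-fold). The count of 6 became 3 without untreated replicate 3 or TNF plus WBG replicate 2, 10 without untreated replicate 2 and 14 without TNF plus WBG replicate 3. Of 8 cytokines 3 rose (6 adjusted over the list alone; camera adjusted p = 0.000445; adjusted p = 0.086 with an estimated correlation), Csf1 (2.59-fold) among them, and 1 rose without TNF plus WBG replicate 1 or 2. Of 13 mitochondrially encoded RNAs 3 fell (6 adjusted over the list alone; camera adjusted p = 0.00174; adjusted p = 0.451 with an estimated correlation). These falls were kept only without untreated replicate 2 (4) or TNF plus WBG replicate 3 (3), and each of the 7 other omissions gave 0, with mt-Atp6 up to adjusted p = 0.117 (without untreated replicate 3) and mt-Nd4 up to 0.135 (without untreated replicate 1). With quantile normalization mt-Atp6 had an adjusted p of 0.349. In all, 1197 genes passed (719 up, 478 down), 105 of them at least 2-fold, and camera called 17 lists. Apart from the lists given above as passing, none of the 17 passed with an estimated correlation. Among lists not described here, the call of oxidative phosphorylation was lost in 5 omissions of a library (camera adjusted p up to 0.293, without untreated replicate 1). Those of NRF2 and antioxidant genes, the Toll-like receptor pathway and the unfolded protein and integrated stress response were each lost in at least 1 omission. The groups did not overlap for 3655 genes (28.1% where chance gives 10%).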

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

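The alternatives for the percent of genes moved back and for single lists, and the precision weighting, were chosen after the results were seen, and all others before the data were examined. No result called here, or under the alternative, reversed its direction in the alternatives run, while several list tests and gene values not called either way changed sign. Where a value below changed, the cause was not tested, except that a 2-fold minimum or fewer libraries can leave fewer calls by construction.

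Between TNF and untreated, 1386 genes became 124 with a 2-fold minimum, and 920 (without TNF replicate 3) to 1299 with 1 library left out. Between TNF plus WBG and TNF, 13 genes became 7 with only the 6 libraries compared, 4 with a 2-fold minimum, and 8 (without untreated replicate 1) to 14 with 1 library left out. Between TNF plus WBG and untreated, 1197 genes became 105 with a 2-fold minimum, and 814 to 1113 with 1 library left out. The 4 genes moved in opposite directions became 1 with only the 6 libraries compared, 2 in limma without trend and 1 with a 2-fold minimum. With 1 library left out they were 2 (untreated 1 or 3, TNF 2, TNF plus WBG 1 or 3) to 7 (TNF 1). The other alternatives, apart from the replicate block, kept these counts within 1.5 times.

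The labels number the replicates 1 to 3 without saying that equal numbers belong together. Correlation of same-number libraries after removal of the group means was -0.07 to 0.11 over 9 pairs, and 0 libraries correlated best with their own number in both other groups, so the libraries were not treated as paired. TNF 1 and TNF plus WBG 1 did correlate best with each other (0.11). With a replicate block the counts were 1159, 8 and 1046 genes, and 2 genes in opposite directions. The replicate block ended the WBG calls of Cbr2 (adjusted p = 0.24), Armt1 (0.237), 2210412B16Rik (0.18), Afg3l1 (0.0734) and Actr3 (0.0535).

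Camera called 13, 7 and 17 lists in the 3 comparisons, 4, 0 and 5 with an estimated correlation, and fry called 22 and 3 in the first 2 (the 3 were the unfolded protein and integrated stress response, interferon-stimulated genes and DNA replication). With 1 library left out the ranges were 11 to 16, 5 to 10 and 14 to 17 lists. The percent of TNF-called genes that moved the opposite way with WBG, 76.0, was 74.8 to 86.3 over the alternatives and 71.1 to 80.1 with 1 library left out. The shared TNF libraries alone gave a simulated mean of 62.5% and at most 65.3% in the reported setting. No alternative was simulated, so these ranges have no baseline of their own.

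Of 3953 alternatives for 210 results of named genes, 3620 kept direction and side of the threshold, 324 lost the call, 4 gained it and 5 changed sign without a call on either side. Of the 166 called results 122 kept the call in every alternative run for them. Tmem184b, Steap4, Tfrc and Cxcl1 were called with WBG in all alternatives run that test genes without a 2-fold minimum, and Saa3 was not with only the 6 libraries compared (0.0502). The depth per gene is not in the file, so its limits were not computed for single genes.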

Other observations

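The tests of a minority of other cells, of failed estimates, of shared noise, of scaling, of TNF exposure and of jumping values below were chosen only after the results they bear on were seen, and so were the genes of the next paragraph and the precision weighting.

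Further genes near the responses above followed the order untreated, TNF, TNF plus WBG, without passing the test for WBG. Slc11a2, an iron transporter, had 14.6 ± 0.39, 25.0 ± 0.50 and 30.1 ± 1.39 FPKM (SD, n = 3), and rose with TNF (adjusted p = 1.53e-05) but did not pass with WBG (log2 0.26, adjusted p = 0.249). Nfkbiz, which encodes IkB-zeta, had 9.54 ± 0.58, 13.3 ± 0.42 and 15.9 ± 1.22 FPKM (adjusted p = 0.00309 with TNF, 0.417 with WBG). Ccl20, a chemokine of the IL-17 response, was listed at 0 in untreated libraries and had 0.59 ± 0.22 and 1.99 ± 0.57 FPKM (adjusted p = 0.0239 with TNF, 0.154 with WBG).

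The libraries labelled as a macrophage line held fibroblast transcripts and almost no macrophage transcripts. Other cells mixed as a minority into a macrophage culture would leave macrophage genes high, yet 2 of 20 macrophage identity genes (Cebpb and Maf) reached a mean of 10 FPKM. Failed estimates for macrophage genes in the processing, if they gave exactly 0, would leave most of them at 0, while 3 of 20 were at 0 in all 9 libraries. The median of that list was 0.02 FPKM, so the count of zeros cannot exclude estimates that failed to values near 0. Of 25 genes that most cells use 24 reached 10 FPKM, which does not bear on a failure limited to macrophage genes. The libraries may come from cells other than the labelled macrophage line: of 22 further blood cell genes, a list written before its values were seen, 2 reached 10 FPKM (Fyb, 43.4, and Lsp1, 19.3), and of 16 further mesenchymal genes 11 did (Lgals1 1108 and Sparc 1055 FPKM). No sort is described, the data do not say which cells these were, and a line that had lost its macrophage program was not tested.

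Genes changed by TNF shifted back toward the untreated level in the WBG libraries, 76.0% of them. Noise that both comparisons share through the TNF libraries was tested in 6 splits, in which separate TNF libraries called the genes and met the WBG libraries. The percent was still 64.2 to 70.5, so most genes moved back when no single TNF library entered both comparisons. A deviation common to all TNF libraries stays in both parts of a split and could give this as well. The split percents were not simulated either, so the splits do not exclude noise shared by the whole TNF group. A difference in scaling between the groups moves TNF-raised and TNF-lowered genes the same way, yet in these splits at least 63.8% of each class moved back. A weaker effective TNF exposure in the cultures that received WBG cannot be told apart from an action of WBG on the response: TNF-raised and TNF-lowered genes both moved back (76.5 and 75.2%), as either could give, and no WBG-only group exists. The part moved back was 6.7% of the TNF change, where simulations with no WBG effect gave up to 8.2%. It was 7.9% with split TNF libraries, a value that was not simulated. With genes weighted by precision it was 10.9%, where the simulations gave a mean of 1.3% and at most 2.0%. The simulated genes vary independently, so these ranges may be too narrow.

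Single genes such as Tmem184b differed by a large step in the WBG libraries. Values that jump between 2 levels in the estimates may give such steps by chance. In all, 137 genes had 3 libraries apart from the other 6 by a log2 gap of at least 0.6 and at least 2 times the range within either part. For 103 of them the untreated libraries were apart, which a response to TNF gives as well, so these are no sign of jumps. For 1, Zmym1, the TNF libraries were apart. Zmym1 lay between 1.67 and 2.41 FPKM in the TNF libraries and between 5.64 and 6.96 FPKM in the other 6. The same caution therefore holds for its fall with TNF and its rise with WBG. For 31 of the 137 the 3 libraries cut across the groups (mean 0.38 and at most 3 genes per set, 81 sets), and for 2, Tmem184b and Tfrc, they were the WBG libraries. Few of the 81 sets held as many as 2 genes. These counts do not exclude a response to WBG, and reads, which would decide, are not analysed here.

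Saa3, Cxcl1 and Steap4 were higher with WBG, and a candidate explanation, not a technical one, is induction of genes reached through IkB-zeta or IL-17. A list of 13 further such genes, written before its values were seen, had 5 measured members, 4 of them higher with WBG (Cebpd 0.35, Zc3h12a 0.29, Map3k8 0.18 and Slc39a14 0.12; Steap1 -0.29). Its camera p was 0.0406 (unadjusted; 0.141 with an estimated correlation) at a median log2 fold change of 0.18 and a mean of 0.13, and 0 of the 5 passed alone. The list is small, and the evidence for it ends with the estimated correlation.

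Each comparison of 3 against 3 libraries has 10 splits, so the share of splits with as many calls cannot go under 0.1. In each comparison 1 split, the real one, gave the most: 1386 genes against at most 5 in the other splits for TNF against untreated, 13 against at most 5 for TNF plus WBG against TNF, and 1197 against at most 2 for TNF plus WBG against untreated. Each of the other splits mixes the 2 groups, which raises the spread within its parts wherever the groups differ. Their counts are therefore lowered by any real difference and do not measure how many calls are false.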
